A study of Mus musculus with 2 samples.

How the data were processed

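RNA was measured by sequencing in 2 libraries of CD4+ T cells sorted from mouse spleen at day 14, 1 library from animals labelled HFD-MI and treated with probucol and 1 from untreated HFD-MI animals. The labels do not say how many animals stand behind each library, nor their genotype; the file headers of both libraries carry the word HypoE, which the labels do not explain. Per the labels' protocols, total RNA was isolated with the miRNeasy Micro Kit, full-length cDNA was made with SMART-Seq HT chemistry, and Illumina libraries were built with a Nextera kit. The labels name no unique molecular identifiers and no stranded counting, so copies made by PCR cannot be removed and reads from overlapping or antisense genes cannot be told apart.

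The deposited values are FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library), 1 value per gene symbol and library, per the file headers. TopHat2 2.1.1, Bowtie2, Cuffdiff 2.2.1 and the genome build mm10 are named in the submitters' processing notes, without the role or order of each tool. The gene annotation, read filters and any further scaling between the libraries are not given in the sources used here. Each table held 24346 symbols. FPKM values are not counts, so no count model was fitted. Fragments shared by near-identical genes (globins, the Hspa1a and Hspa1b pair, kallikreins, immunoglobulin-like and olfactory receptor families) could have been split between copies, and values of such genes are uncertain.

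Depth was estimated from the values. For genes with 1 annotated transcript of 800 to 10000 bp, low FPKM values multiplied by transcript length fell on steps, and the step (the worth of 1 fragment) was fitted together with a length subtracted for the fragment size. The fitted step was 0.101 FPKM per fragment at 1 kb with probucol and 0.100 untreated, with 210 bp subtracted. Of the low values, 75.8% and 77.2% lay within 0.1 of a whole number of fragments, where 20% would by chance. Summed over the 23310 symbols with a length in GENCODE release M21 (GRCm38, the same assembly as mm10), this gave an estimated 9.56e+06 fragments with probucol and 9.60e+06 untreated. Fragment numbers per gene were estimated in the same way from the median length of its annotated transcripts. From these, 95% intervals of the fold between libraries were computed as exact (Clopper-Pearson) binomial intervals. They cover counting error only, not differences between animals, sorts or library preparations, and are approximate for genes with several transcripts.

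With 1 library per group there is no replicate spread, and no p-value was computed. The log2 ratio of probucol over untreated was taken on FPKM + 1, which understates changes of low genes, while folds printed for single genes are ratios of the FPKM values themselves. Genes with a mean FPKM over both libraries of 1 or more were compared, and a log2 ratio of at least 1 in either direction was counted as at least 2-fold. The 32 gene lists, the counting rule and the rule for named genes were fixed before the data were examined. For each list with at least 3 measured members, the median log2 ratio was set against the medians of 10000 random lists of the same size matched on mean FPKM in 20 bins. A percentile under 2.5 or over 97.5 is described as outside the middle 95% of random lists; it describes these 2 libraries, and genes are not replicates. Intervals of list medians are order-statistic 95% intervals across genes. Named genes were the 12 highest and 12 lowest ratios at a mean FPKM of 10 or more, up to 4 members of each list with the largest ratios in either direction, a fixed set of T cell, lipid and marker genes, and the 5 highest genes listed at 0 in the other library, per direction; predicted, clone-named and small RNA genes and receptor segments were left out of the first and last groups. For length, not every such gene is printed, and some genes of the fixed set and the lists are not reported here. Genes named outside this rule are said to be chosen after their values were seen. The mitochondrially encoded list and single list members whose symbols found no match, such as Ighm, Ighd, Igkc and Ly6g, were not analysed here.

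On data simulated for the probucol and untreated comparison over 10691 genes, 94.5% of 200 genes changed 4-fold were recovered, with 23 unchanged genes called. Of 200 simulated unchanged lists, 5.0% fell outside the middle 95%, and 100.0% of lists shifted by 0.5 on the log2 scale were found. Simulated genes varied independently, with added noise of 1 size for all, and unchanged lists were drawn at random. Their rate was thus set by design. These figures do not cover lists of genes that vary together, and are not error rates of the real comparison. Alternatives were other pseudocounts (0.1 and 5), other filters on low values, rescaling both libraries to the same sum, centring on the median gene, leaving out genes at 0, and the mean in place of the median; removal of the trend on transcript length and GC content, leaving out predicted and small RNA symbols, and leaving out list members shared with another list were added after the data were examined. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.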

Results

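Gene expression was measured by RNA sequencing in CD4+ T cells sorted from the spleens of HFD-MI mice, a model that the series title places in the setting of remodelling after myocardial infarction. One group was treated with probucol, a cholesterol-lowering drug with antioxidant activity, and the other was untreated. Each group had 1 library, taken at day 14. The number of fragments in genes, estimated from steps in the low FPKM values, was 9.56e+06 with probucol and 9.60e+06 untreated, PCR copies included. A transcript of 1 kb at 1 FPKM rests on about 7.84 fragments with probucol and 7.88 untreated. T cell identity genes were abundant and close in both libraries. Cd4 stood at 334 FPKM with probucol and 284 FPKM untreated, and Cd3e, a chain of the T cell receptor complex, at 478 and 494 FPKM. Cd8a, the marker of the other main T cell lineage, was at 0.139 and 0.276 FPKM. The gene of the other CD8 chain, Cd8b1, was higher, at 15.9 and 19.6 FPKM, so these 2 genes do not settle how pure the sort was. The libraries differed in the number of genes seen at all. With probucol 14289 of the 24346 symbols were above 0, against 16876 untreated, and 3289 symbols were at 0 with probucol only, against 702 at 0 untreated only. Among 1576 olfactory, vomeronasal and taste receptor, keratin-associated and beta-defensin genes, 73 (4.63%) were above 0 with probucol and 442 (28.0%) untreated. All comparisons below are between these 2 libraries, have no replicate check, and carry counting intervals only.

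The design asks which genes differ in splenic CD4+ T cells when HFD-MI mice receive probucol. Most of the transcriptome was close between the libraries: 10279 of 10663 genes (96.4%) lay within 2-fold. At least 2-fold higher with probucol were 173 genes (1.62%), and at least 2-fold lower were 211 (1.98%). At a mean FPKM of 10 or more, the lowest ratios included globin genes and the effector chemokine Ccl5, and the highest included chaperones. These groups were picked out after the values were seen, and both ends of the ranking were mixed. Zfp488, at 6.54 and 37.9 FPKM, and Olfr856-ps1, at 11.1 and 69.3 FPKM, had lower ratios than Ccl5. Ly6k, at 70.3 and 20.5 FPKM, and Tmem181b-ps, at 21.6 and 6.08 FPKM, had higher ratios than the chaperone-related Ahsa2 and Hspa4l. Ccl5 (chromosome 11, 83525778 to 83530518, mm10) was at 131 FPKM with probucol and 459 FPKM untreated, 3.51-fold lower (95% counting interval 3.14 to 3.92). Mt1, a metal-binding metallothionein, was at 2.70 and 24.5 FPKM, 9.07-fold lower (5.0 to 19.2). Hsph1 (chromosome 5, 149614287 to 149636376), a chaperone of the HSP110 family, was at 299.8 and 87.4 FPKM, 3.43-fold higher (3.28 to 3.58). Its relatives in protein folding Ahsa2 and Hspa4l were 2.75-fold (2.55 to 2.96) and 2.77-fold higher (2.53 to 3.04). The nuclear noncoding RNA Malat1 was 2.57-fold higher (2.27 to 2.91), at 234 against 91.1 FPKM. Plod1, a collagen lysyl hydroxylase, was 3.99-fold higher (3.15 to 5.09). Slfn8, a Schlafen family member, was 2.92-fold higher (2.45 to 3.48), and Cdk5rap1 was 3.43-fold lower (2.88 to 4.12). Several genes at the ends of the ranking belong to families not typical of T cells. The glucagon gene Gcg was 27.1-fold lower (13.4 to 63.0), the kallikrein Klk1b22 was at 38.3 against 0.338 FPKM, and Mrgpra6 was 5.25-fold lower (4.66 to 5.94). Klk1b22 rests on about 245 and 2 fragments, and kallikreins share sequence, so its value is uncertain. Predicted, clone-named, small RNA and receptor segment symbols made up 54 of the 173 higher and 63 of the 211 lower genes. The counts depend on the setting: they were 313 and 357 with pseudocount 0.1, 55 and 64 with pseudocount 5, and 83 and 96 at a mean FPKM of 5 or more.

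**Figure D1:**
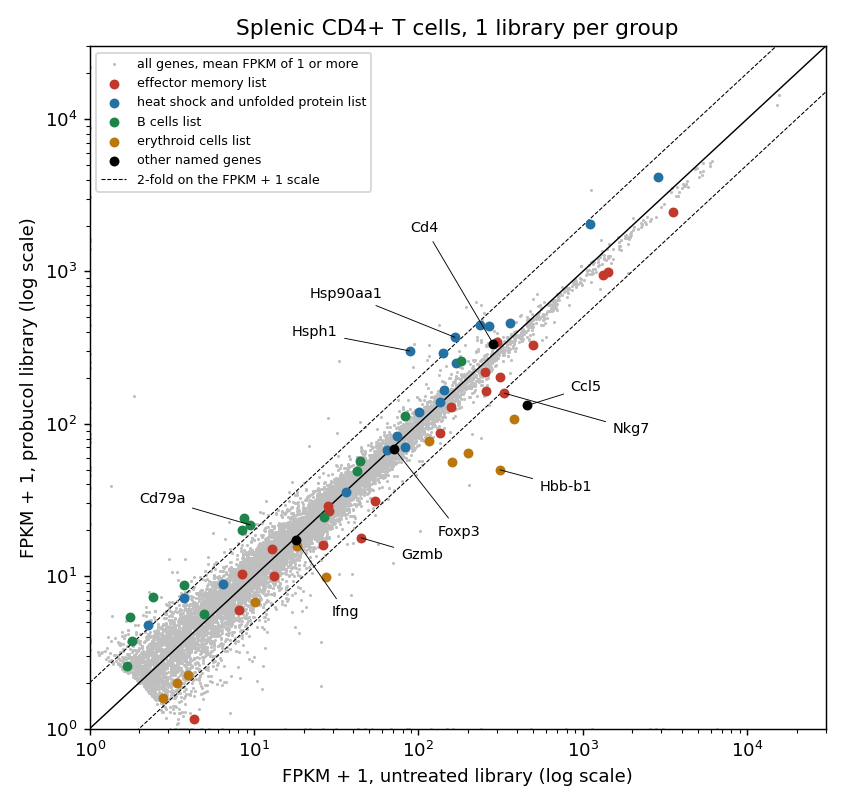
FPKM + 1 of each gene in the untreated library (x axis, log scale) and the probucol library (y axis, log scale), with 1 point per gene with a mean FPKM of 1 or more, 4 gene lists in colour and dashed lines at 2-fold. Hsph1 and Hsp90aa1 lie above the upper line, Ccl5, Gzmb, Nkg7 and Hbb-b1 below the lower one, and Ifng, Foxp3 and Cd4 near the diagonal.

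The series concerns CD4+ T helper subsets, and Th1 cells in particular. The signature cytokine and transcription factor of Th1 cells were at nearly equal levels. Ifng was at 16.2 FPKM with probucol and 17.0 FPKM untreated, a ratio of 0.951 (0.762 to 1.19), and Tbx21, which encodes T-bet, was at 16.2 and 15.9 FPKM, a ratio of 1.02 (0.879 to 1.18). Most other members of the Th1 list were lower. Of its 18 measured genes, 14 were lower and 4 higher, with 4 lower by at least 2-fold and 0 higher by that much. Besides Ccl5 these were the chemokines Ccl3, 4.54-fold lower (2.05 to 10.1), and Ccl4, 2.35-fold lower (1.78 to 3.19), and Il18rap, a subunit of the interleukin 18 receptor, 2.93-fold lower (2.27 to 3.77). The chemokine receptor Cxcr3 was 1.32-fold lower (1.24 to 1.41). Of the higher members, Tnf and Runx3, named after their values were seen, were 1.63-fold (1.26 to 2.11) and 1.45-fold higher (1.30 to 1.62). Il2 was at 2.99 and 3.52 FPKM, with an interval from 2.01-fold lower to 1.46-fold higher. The list's median log2 ratio was -0.16 (-0.87 to -0.01), at percentile 1.43 of random lists. It lay inside the middle 95% with pseudocount 5, at a mean FPKM of 5 or more, and without members shared with other lists. In these libraries the medians of the B cell, erythroid and natural killer lists were 0.83, -0.82 and -0.20.

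The regulatory T cell list had a median of -0.16 (-0.50 to -0.06, percentile 1.26), with 16 of 20 members lower and 0 past 2-fold. Its master regulator Foxp3 was at 67.5 and 70.3 FPKM, a ratio of 0.960 (0.899 to 1.02), while the costimulatory receptors Tnfrsf4 and Tnfrsf18 were 1.69-fold (1.59 to 1.79) and 1.61-fold lower (1.54 to 1.69), and Ebi3 was 1.87-fold lower (1.39 to 2.58). Klrg1 was 1.65-fold lower, at 44.2 and 72.9 FPKM. Il2ra and Ctla4 were at 0.879 (0.737 to 1.05) and 0.926 (0.845 to 1.01) of their untreated level. With the mean in place of the median, or without shared members, the regulatory list fell inside the middle 95%. The Th2 list (median -0.10, percentile 13.4), the Th17 list (-0.08, percentile 21.5) and the follicular helper list (0.06, percentile 78.3) lay inside it. The Th2 transcription factor Gata3 was 1.19-fold lower (1.12 to 1.28) and the chemokine receptor Ccr8 1.91-fold lower (1.69 to 2.17). Bcl6, the follicular helper transcription factor, was at 10.6 and 7.17 FPKM, and Cxcr5 was 1.27-fold higher (1.16 to 1.38). B cells also express both, and the medians of the B cell and erythroid lists were 0.83 and -0.82.

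The effector memory list was lower with probucol. Of its 21 genes, 4 were higher and 17 lower, 3 of the latter by at least 2-fold. The cytotoxic granule genes led it: Gzmb was at 16.8 and 43.8 FPKM, 2.60-fold lower (2.21 to 3.07), Nkg7 at 158 and 333 FPKM, 2.11-fold lower (1.95 to 2.28), and Gzma at 0.150 and 3.28 FPKM, on about 1 and 24 fragments. Ly6c2 was 1.78-fold lower (1.43 to 2.24). Cd44, the usual surface marker of antigen-experienced T cells, was at 28.0 and 27.3 FPKM, a ratio of 1.03 (0.916 to 1.15). The list's median log2 ratio was -0.52 (-0.66 to -0.22), below the medians of all 10000 random lists. Without Gzma, Gzmb, Gzmk and Nkg7, a split chosen after the values were seen, the other 17 genes had a median of -0.44 (-0.61 to -0.09). With the mean in place of the median, the list's value of -0.50 was at percentile 5.69. The naive or central memory list had a median of -0.13 (-0.22 to 0.05, percentile 10.6), with Bach2 1.37-fold higher (1.19 to 1.56). The medians of the inhibitory receptor list (-0.24, -0.50 to 0.15, percentile 0.58) and the chemokine and adhesion receptor list (-0.18, -0.29 to -0.01, percentile 0.55) were also lower. Havcr2, at 0.996 and 2.66 FPKM, was 2.67-fold (1.66 to 4.41), Tigit 1.42-fold (1.26 to 1.58) and Ccr4 1.71-fold lower (1.32 to 2.22). Of the inhibitory receptors, 9 of 11 were lower and 2 higher, among the latter Cd160, 1.41-fold higher (1.11 to 1.78). Both lists lay inside the middle 95% by their mean and without shared members, and the inhibitory list also at a mean FPKM of 5 or more. T cell receptor signalling genes had a median of 0.02 (percentile 95.9, above the middle 95% at a mean FPKM of 5 or more and without shared members) and immediate early genes of -0.01 (percentile 73.3). In these libraries the B cell list had a median of 0.83, the erythroid list of -0.82 and the natural killer list, which also holds Gzma, of -0.20, with Klrd1, Klrk1 and Eomes 5.10-fold (2.49 to 13.2), 3.03-fold (1.36 to 7.98) and 1.62-fold lower (1.22 to 2.15).

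Interferon-stimulated and cell cycle genes were lower with probucol. In the type I interferon response list 20 of 22 genes were lower, 4 by at least 2-fold, and the median was -0.45 (-0.80 to -0.15), below all random lists. The antiviral genes Rsad2, Ifi44 and Ifit3 were 3.73-fold (2.53 to 5.53), 3.10-fold (2.17 to 4.45) and 2.59-fold lower (1.93 to 3.54). Oas2 went the other way, 4.04-fold higher (2.91 to 5.79), at 4.85 FPKM with probucol. The interferon gamma response list had a median of -0.00271 (-0.14 to 0.11, percentile 59.2), with 10 genes higher and 11 lower and none of the 21 past 2-fold; Gbp4, an interferon-inducible GTPase, was 1.30-fold higher (1.23 to 1.37) and Irgm2 1.42-fold lower (1.29 to 1.57). In the cell cycle list 17 of 20 genes were lower, with a median of -0.47 (-0.62 to -0.30), below all random lists. The mitotic genes Ccnb2, Ube2c, Cdk1 and Cdc20 were 2.48-fold (1.90 to 3.25), 1.96-fold (1.56 to 2.48), 1.90-fold (1.38 to 2.59) and 1.72-fold lower (1.36 to 2.18). The type I interferon and cell cycle lists lay below the middle 95% in all 11 alternatives, among them centring, which cannot change a percentile. Beside them stood the B cell list at 0.83 and the erythroid list at -0.82.

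Chaperone genes were higher with probucol. In the heat shock and unfolded protein list 17 of 19 genes were higher, 4 by at least 2-fold, and the median was 0.55 (0.15 to 0.95), above all 10000 random lists. Hsp90aa1, the inducible cytosolic HSP90, was at 369 and 166 FPKM, 2.23-fold higher (2.15 to 2.30). Hspd1, the mitochondrial chaperonin HSP60, was at 291 and 141 FPKM, 2.06-fold higher (1.98 to 2.16). Hspa1a was at 3.79 and 1.27 FPKM, 2.98-fold higher (2.02 to 4.51), with its share of fragments uncertain because of its near-identical copy. By its mean of 0.57 the list was at percentile 95.8. Apoptosis regulators had a median of 0.00475 (percentile 47.7), with Bcl2, which restrains cell death, 1.87-fold higher (1.79 to 1.96) and the pro-apoptotic Pmaip1 2.09-fold lower (1.61 to 2.71). The medians of the B cell and erythroid lists in these libraries were 0.83 and -0.82.

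The lists of lipid and redox genes, the pathways nearest to the known actions of probucol, had medians from -0.10 to -0.05, with single members further apart. The cholesterol synthesis and uptake list had a median of -0.10 (-0.18 to 0.15, percentile 4.43), with 12 of 20 genes lower. The mevalonate pathway kinases Mvk and Pmvk were 2.96-fold (1.93 to 4.76) and 2.26-fold lower (1.72 to 2.96), and Sqle 1.77-fold higher (1.29 to 2.45). The list lay below the middle 95% after rescaling to equal sums or with no filter on low values. The cholesterol efflux list had a median of -0.05 (percentile 23.6). Abca1, the exporter of cholesterol to apolipoproteins, had a ratio of 1.02 (0.904 to 1.15), Apoe of 1.09 (0.831 to 1.43), and Scarb1, a receptor for high-density lipoprotein, of 0.722 (0.501 to 1.02). Abcg1 was 1.26-fold lower (1.19 to 1.34) and Soat1 1.63-fold higher (1.40 to 1.91). Nr1h3, which encodes the oxysterol receptor LXR alpha, was 4.52-fold higher (1.75 to 12.9), at 1.70 and 0.376 FPKM, on about 26 and 6 fragments. The genotype of the animals, which could bear on Apoe, Scarb1 and other lipid genes, is not given in the labels. In these libraries the B cell, macrophage and erythroid lists had medians of 0.83, 0.28 and -0.82. The antioxidant list had a median of -0.07 (percentile 28.5), with 13 of 20 genes lower and 0 past 2-fold; Hmox1 was 1.54-fold lower (1.31 to 1.83) and Gclc 1.32-fold higher (1.18 to 1.47). Glycolysis genes had a median of -0.19 (-0.36 to -0.08, percentile 0.77), with 14 of 16 lower, led by Tpi1 at 1.76-fold (1.62 to 1.92) and Slc16a3 at 1.82-fold lower (1.47 to 2.28); by the mean the list lay inside the middle 95%. Nuclear oxidative phosphorylation genes had a median of -0.10 (percentile 30.3). Ribosomal protein genes had a median of -0.17 (percentile 0.53), which became -0.042 (percentile 18.1) once the trend on transcript length and GC content was removed.

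Markers of other blood cells differed between the libraries. B cell genes were higher with probucol: 13 of 14 measured genes were higher, 7 of them by at least 2-fold, and the median was 0.83 (0.22 to 1.49), above all random lists. Cd79a and Cd79b, the signalling chains of the B cell receptor, were at 20.7 and 19.0 FPKM with probucol against 8.48 and 7.46 FPKM, 2.44-fold (1.94 to 3.11) and 2.55-fold higher (1.97 to 3.33). Cd22 was 5.74-fold higher (3.81 to 9.16). Erythroid genes were lower: all 11 were lower, 5 by at least 2-fold, with a median of -0.82 (-1.82 to -0.59), below all random lists. The globin genes Hbb-b1, Hba-a2 and Hba-a1 were at 48.9, 106 and 55.3 FPKM with probucol and 312, 378 and 158 FPKM untreated, with fragments of near-identical copies possibly split between them. The macrophage list had a median of 0.28 (-0.07 to 0.51, percentile 98.5), with 10 of 15 genes higher and 5 lower. Its summed FPKM was 417 with probucol and 448 untreated. Csf1r was 2.02-fold higher (1.53 to 2.72), and Lyz2 was at 125 and 132 FPKM. The macrophage list lay inside the middle 95% with pseudocount 5 or by the mean. The neutrophil list had a median of 0.21 (percentile 97.3), with the granule enzymes Elane and Mpo 4.27-fold (2.62 to 7.03) and 2.59-fold higher (2.04 to 3.29); it lay above the middle 95% with pseudocount 5, with no filter, without predicted and small RNA symbols, and with the length and GC trend removed. The natural killer list had a median of -0.20 (percentile 5.90), with Klrd1, a natural killer receptor subunit, 5.10-fold lower (2.49 to 13.2); it lay below the middle 95% by the mean and with pseudocount 5, and its median was above 0 with no filter (0.0065) and at a mean FPKM of 5 or more (0.20). The dendritic cell list had a median of -0.11 (percentile 20.4) and the plasma cell list of 0.30 (percentile 92.7, over 4 genes). Xcr1, the marker of the dendritic cells named in the series title, was at 0.992 and 1.86 FPKM, 1.87-fold lower (1.27 to 2.79). Of the CD8 T cell list only Cd8b1 passed the filter, at 15.9 and 19.6 FPKM, and of the platelet list only Pf4, at 2.64 and 0.526 FPKM, and Ppbp, at 1.15 and 1.26 FPKM. Of the 29 lists with at least 3 measured genes, 13 lay outside the middle 95% of random lists, 3 above and 10 below. If genes within a list varied independently, 1.45 would by chance. Genes of 1 cell type or pathway can vary together, so 13 against 1.45 does not measure an excess over chance.

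**Figure D2:**
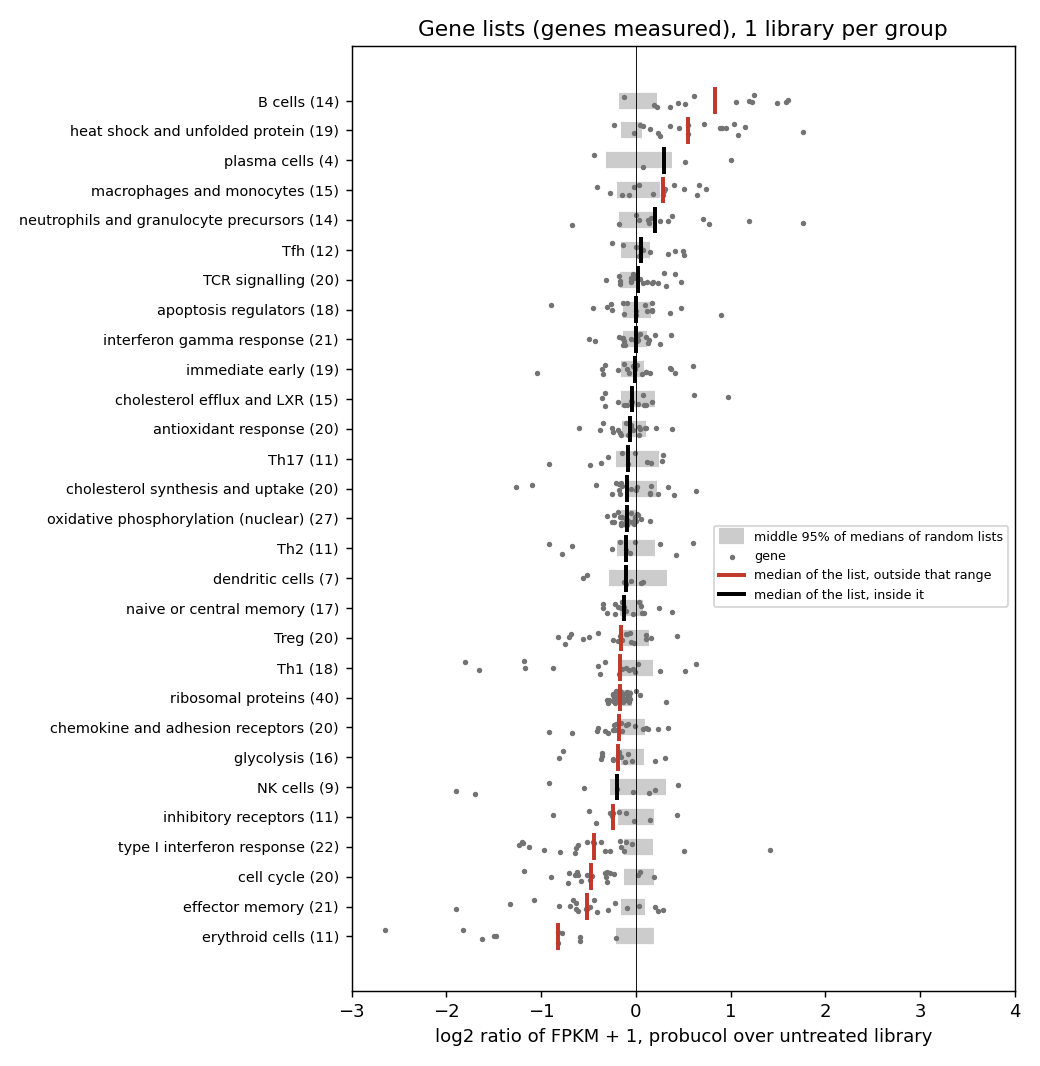
Log2 ratio of FPKM + 1, probucol over untreated (x axis), of each measured gene (grey points) in 29 gene lists (rows, with the number of genes measured), the median of each list (vertical bar, red where outside) and the middle 95% of medians of random lists matched on mean FPKM (grey band). The B cell (0.83) and heat shock (0.55) lists lie highest and the erythroid (-0.82), effector memory (-0.52), cell cycle (-0.47) and type I interferon (-0.45) lists lowest.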

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

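The removal of the length and GC trend and the settings without predicted and small RNA symbols or without shared members were chosen after seeing the data. With probucol higher and lower, they were 313 and 357 with pseudocount 0.1, 55 and 64 with pseudocount 5, and 83 and 96 at a mean FPKM of 5 or more, against 173 and 211; fewer genes (8042) enter under the last filter, and a larger pseudocount shrinks the ratios of low genes by construction. Under rescaling, centring, no filter, leaving out genes at 0 and leaving out predicted and small RNA symbols, both counts stayed within 1.5 times. Of the list medians, 3 values left their order-statistic interval: the erythroid list with pseudocount 5 (-0.56), and, with the length and GC trend removed, the oxidative phosphorylation list (-0.0080) and the ribosomal list (-0.042). Centring on the median cannot change a list's percentile, so among the 11 alternatives it is no check of the counts that follow. The B cell, erythroid, cell cycle and type I interferon lists stayed outside the middle 95% of random lists in all 11 alternatives. The effector memory, heat shock and glycolysis lists did so in 10, the exception being the mean over members. The regulatory, ribosomal, chemokine receptor and macrophage lists stayed outside in 9 and the Th1 and inhibitory receptor lists in 8, and the T cell receptor, cholesterol synthesis, natural killer and neutrophil lists moved outside in 2, 2, 2 and 4 (the causes were not tested). No list outside that range changed sign in the alternatives run. Named genes were rerun only with other pseudocounts, rescaling and centring. A pseudocount cannot change the sign of a ratio, and rescaling and centring moved ratios too little to reverse a 2-fold difference. The signs of named genes were therefore not put to a test. Scaling moved the median of all genes by under 0.1 on the log2 scale (0.04 after rescaling, 0.02 as deposited). No paired analysis was possible because each group has 1 library, and no replicate could be left out. Depth limits genes near 1 FPKM, where a 1 kb transcript has about 7.84 fragments with probucol and 7.88 untreated; PCR copies and differences between animals are not covered by the counting intervals.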

Other observations

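The tests of CD8 T cells, natural killer cells, immediate early genes and depth were chosen after the values they use had been seen; those of length and GC content, co-chaperones and untranscribed gene families were written first. Most co-chaperones and related genes outside the fixed list were also higher with probucol. A list of 32 genes, called the co-chaperone list, was written before their values were looked at. It held HSP90 and HSP70 partners and chaperonin subunits. It also held the chaperones Hspa4, Hspa9 and Trap1, the heat shock factors Hsf1 and Hsf2, and Hsbp1. Of the 32, 24 were higher, 0 of them by at least 2-fold, and the list had a median log2 ratio of 0.30 (0.08 to 0.52). Chordc1, Stip1, Bag3, Ahsa1, Ahsa2 and Hspa4l, already seen to be higher, were left out of it. As examples chosen after their values were seen, Fkbp4 was at 299.9 and 175.6 FPKM, Cacybp at 238.6 and 145.5, St13 at 180.4 and 109.9, and the chaperonin subunit Cct7 at 351 and 225 FPKM. Among the lower members, also chosen after their values were seen, Unc45a was at 33.2 and 39.8 FPKM and Sugt1 at 52.8 and 61.5 FPKM. Of those left out, Chordc1, Stip1 and Bag3 were at 262, 528 and 21.5 FPKM with probucol against 111, 249.8 and 10.2 FPKM untreated. Genes listed at 0 in 1 library were low in the other: Il4i1 was at 2.30 FPKM and Trem3 at 2.86 FPKM with probucol, and Orm1 at 3.21 FPKM and Apoc1 at 3.12 FPKM untreated.

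In the effector memory list, transcript length or GC content bias was considered because the log2 ratio had a Spearman rho of 0.21 with length and -0.14 with GC content across 10269 genes, which are not independent replicates, and the list's genes are short (median 1166 bp against 2501 bp). With that trend removed the list's median was -0.47 (-0.55 to -0.13), still below all random lists, while the ribosomal list returned inside. This argues against the trend as the whole cause, though a part of the shift may come from it. The interval does not reach the stricter bound of -0.26 set beforehand. Before removal the interval (-0.66 to -0.22) did not reach it either, so that bound cannot weigh the trend. Fewer CD8 T cells stay open: Cd8a, lower by 0.0419% of the FPKM that Ccl5 was lower by, rests on about 4 and 8 fragments, and Cd8b1 was 1.23-fold lower (1.02 to 1.49), at 15.9 and 19.6 FPKM. Fewer natural killer cells stay open, since list members went both ways: Klrd1, Klrk1 and Eomes were 5.10-fold (2.49 to 13.2), 3.03-fold (1.36 to 7.98) and 1.62-fold lower (1.22 to 2.15), while Prf1 was 1.37-fold higher (1.25 to 1.51) and Ncr1, Klrb1c and Klre1, all under 2 FPKM, were together higher (a fall of -0.856% of that of Nkg7), the last 4 genes being named after their values were seen. A change within CD4+ T cells, in subset shares or in expression, stays open as a hypothesis, as do differences between the animals or sorts behind the 2 libraries, since treatment and library cannot be separated with 1 library each.

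The higher median of the chaperone list remained after removal of the length and GC trend. It was 0.49 (0.23 to 1.03) against 0.55 before, above all random lists. The interval did not clear the stricter bound of 0.27 set beforehand. Before removal the interval (0.15 to 0.95) did not clear it either, so that bound cannot weigh the trend here. The new co-chaperone list lay at percentile 100 of random lists, above all 10000, so the pattern is not limited to the genes first listed and is consistent with a wider chaperone programme. Warmer or longer handling of 1 sample is a candidate explanation, and immediate early genes do not decide it: their median was -0.0053 with members on either side, such as Nr4a2 at 3.05-fold lower and Cd69 at 1.52-fold higher. Treatment with probucol and differences between animals stay open and untested.

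Fewer genes were seen with probucol, and a lower number of fragments is argued against by the estimated totals, with a ratio of 1.00366, untreated over probucol; the number of distinct molecules before PCR is unknown. Reads from untranscribed DNA in the untreated library were tested with 1576 olfactory, vomeronasal and taste receptor, keratin-associated and beta-defensin genes, families silent in most tissues. With probucol 73 of them were above 0 (4.63%, exact 95% binomial interval 3.65 to 5.79) and untreated 442 (28.0%, 25.8 to 30.3), with a summed FPKM of 40.4 and 280.6, or 20.3 and 174.9 without the 3 highest genes in each library. Among all symbols, 3289 of the 10057 at 0 with probucol were above 0 untreated. The test thus does not set these families apart from other genes near the floor. Carry-over of genomic DNA or unspliced transcripts in the untreated library stays a candidate explanation. These 2 sources were not separated, and no biological explanation was tested. The mean level of the family genes was 0.0256 FPKM with probucol and 0.178 FPKM untreated, small beside the differences of abundant genes such as Ccl5 (131 and 459 FPKM). It may account for genes near the floor. An even level this low would not give Olfr613 its 3.64 and 16.8 FPKM, Olfr856-ps1 its 11.1 and 69.3, or Vmn1r58 its 5.31 and 19.7. These genes were also lower with probucol, and whether the same source reaches genes well above the floor was not tested.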
